A study of Mus musculus with 6 samples.

How the data were processed

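Spleen T cells of FVB mice were stimulated with anti-CD3 and anti-CD28 beads and treated at the same time with 50 µM urolithin A or DMSO for 48 h, per the labels' protocols. Total RNA was extracted with a column kit and 200 ng of it went into an mRNA-focused stranded library for each sample, per the labels' protocols. Each group held 3 libraries, a to c. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.20.0.422, reads were checked with FastQC and aligned to mm10 with STAR 2.5.2a, and the submitters used DESeq2. The counting program, its use of the read strand and the gene annotation are not given in the sources used here. The unit of the deposited table is recorded here as other, since its columns write whole numbers with a decimal comma and no label names their unit. Read with the decimal comma, all values of the 6 columns used were whole numbers at or above 0, and they were treated as read counts per gene. The deposited table has an ID, a symbol, coordinates and a gene class for each of 18828 genes. Of these, 18725 IDs are shared with the GENCODE M21 annotation of mm10, and 385 (2.06%) have the same start and end there, so coordinates are given as the table holds them.

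Of the 2 deposited files 1 was used, since both hold the same values. The 3 per-library columns in it that match none of the labelled samples were left out. The 6 matched columns were joined to the labels by group and letter. Total counts ran from 12738059 to 19081219 per library, and 17948 to 18305 genes had at least 1 count. Between libraries of a group, ribosomal RNA genes set aside, counts differed by a chi-square per degree of freedom where counting error alone gives 1. It was 5.66 to 15.7 in pairs without DMSO library b. In pairs with it the values were 32.5 and 34.1, but the scaling allowed again for ribosomal RNA counts already removed. Those values therefore overstate the spread, and pairs with urolithin A library a are affected to a lesser degree. Intervals from counting error alone were used only for the share of Rn18s. Those intervals are exact binomial intervals at the 95% level.

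The groups, tests, gene lists and the rule for naming genes were fixed before the data were examined. The test fixed first was an edgeR quasi-likelihood fit, which was not run. The check of units reads no decimal commas, so the unit was recorded as other, and count models were closed to it, although the values themselves did not prevent that fit. The limma voom fit, which had been fixed as an alternative, was used instead. The test that had been fixed for values other than counts, limma with a trend on log2 values with 1 added, was run on CPM as an alternative. Genes entered the test with at least 10 counts in a library of median size in at least 3 libraries and at least 15 counts in all, which kept 14444 genes and 99.9% of the counts of every library. Scaling factors were trimmed means of M values, with 30% of M and 5% of A trimmed on each side, computed by code written for the purpose. CPM are counts scaled to 1e6 per library, with the tested genes' total count times the factor as library size. Log2 fold changes came from voom (offset 0.5) and lmFit with robust eBayes in limma 3.58.1 under R 4.3.3, with group as the only term, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. SE is the moderated standard error. Values are means ± SD of 3 libraries.

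Of 41 fixed gene lists, the 32 with at least 5 tested members were tested with camera at a preset correlation of 0.01, run on the voom values and weights in place of the log2 CPM fixed at first, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Camera at the preset correlation assumes little shared variation between the genes of a list, and its degrees of freedom follow the number of genes tested. With an estimated correlation, camera uses the few residual degrees of freedom of the 6 libraries. Its p-values are then larger even where the genes of a list share no variation. Counts of members that passed are given over all genes tested and adjusted over the list alone. Genes were named by a rule. From the called genes whose groups did not overlap and whose mean CPM was at least 5 in the higher group, clone and prediction names and receptor segments set aside, it took the 10 with the largest and the 10 with the smallest log2 fold change. From each tested list it took the 2 members with the smallest p in the majority direction and 1 in the other, and 13 genes were fixed by name. The rule gave 120 genes with a test.

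The procedure was tested on simulated counts of 14444 genes, with the median spread of genes at a similar level in the data. Of 100 genes changed 1.5-fold 67 were recovered, and of 100 genes changed 2-fold 87. Of the genes called, 5.68% were unchanged ones. A list of 25 genes shifted 1.3-fold was called, and 0 of 31 unshifted lists were. The simulated genes varied independently, and far fewer were changed than the data called. In the data the estimated correlation was 0.63 for the ribosome biogenesis list. The simulation therefore does not show how often camera calls unshifted lists of correlated genes. Alternatives were another size factor, library size alone, other count filters, limma with a trend and other added constants, stricter thresholds, the letter as a block, each library left out in turn, fry and an estimated correlation. After seeing the data 4 more were added, without ribosomal RNA genes, without DMSO library b and urolithin A library a, protein-coding genes only, and lists without shared members.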

Results

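Gene expression was measured by RNA sequencing in T cells isolated from the spleens of FVB mice, an inbred laboratory strain. The cells were stimulated for 48 h with beads that carry antibodies to CD3 and CD28, which stand in for antigen and costimulation, and were exposed at the same time to 50 µM urolithin A or to DMSO, its solvent. Urolithin A is a compound that gut bacteria make from plant ellagitannins and is known to induce mitophagy, the removal of mitochondria by autophagy. Each group held 3 libraries, lettered a to c. The deposited table listed 18828 genes, of which 52 had no count in any of the 6 libraries. The total count was 16469483, 17282867 and 18077217 in DMSO libraries a, b and c, and 19081219, 16912031 and 12738059 in urolithin A libraries a, b and c. The labels do not say whether the letters mark separate animals or cultures, so p-values measure the spread between these samples, which may be technical. The 18S ribosomal RNA gene Rn18s took 17.6% of the counts of DMSO library b (95% exact binomial interval 17.57% to 17.60%) and 3.97% of those of urolithin A library a (3.97% to 3.98%). In the other libraries its share lay between 0.0687% (0.0675% to 0.0700%) and 0.887% (0.882% to 0.891%), and these intervals cover counting error only.

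The comparison asked how urolithin A alters the transcriptome of T cells during their activation and differentiation, with the genes of memory T cells, of mitophagy and of Wnt signalling in view. After 48 h the transcripts of p53 target genes, of interferon response genes and of naive and central memory T cell genes were higher with urolithin A than with DMSO. With an estimated correlation the p53 targets kept their call in camera (adjusted p = 0.0284), while adjusted p = 0.0779 for the interferon list and 0.221 for the naive list. Transcripts for glycolysis, for the hypoxia response, for the ATF4 amino acid response and for ribosome biogenesis were lower. Of these, glycolysis kept its call in camera with an estimated correlation (adjusted p = 0.0284), while adjusted p = 0.221 for the hypoxia and ATF4 lists and 0.334 for ribosome biogenesis. That run also rests on the few residual degrees of freedom of the 6 libraries. A call lost in it therefore does not show that the genes of a list share variation. Of 14444 genes tested with limma voom, 4871 (33.7%) had an adjusted p under 0.05, with 2560 higher and 2311 lower under urolithin A. The change reached 2-fold for 609 of the higher genes and for 301 of the lower genes, and the median absolute log2 fold change of the called genes was 0.50. The 3 values of each group did not overlap for 46.8% of the genes tested, where chance alone gives 10%, and for 97.8% of the called genes. Between libraries of a group the log2 values correlated across genes with r of 0.984 to 0.991, and between groups with r of 0.969 to 0.976 (genes are not independent replicates). The first principal component held 55.6% of the variance. When libraries were scaled to their total count alone, 3169 genes were called and 70.6% of them were higher, against 52.6% with the main scaling. Without DMSO library b and urolithin A library a, an alternative chosen after seeing the data, 2522 genes were called, of which 1330 were higher and 1192 lower.

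The gene with the steepest rise among those that met the naming rule was Gria3, a glutamate receptor subunit, at 0.374 ± 0.219 CPM (SD, n = 3) with DMSO and 7.45 ± 0.666 CPM with urolithin A, a log2 fold change of 4.37 ± 0.36 (SE). Tnfsf4, which encodes the costimulatory ligand OX40L, rose from 5.16 ± 0.546 to 88.7 ± 6.94 CPM, a 17.2-fold increase (log2 fold change 4.11 ± 0.14, limma adjusted p = 6.88e-11). Serpine2, a serine protease inhibitor, rose from 10.4 ± 1.07 to 111 ± 12.8 CPM (log2 fold change 3.42 ± 0.12). Ckmt1, the mitochondrial creatine kinase, and Ak1, an adenylate kinase, rose by 4.18 ± 0.36 and 3.22 ± 0.24 on the log2 scale. The other genes among the 10 largest rises were Robo3, Eda2r, Cox6b2, Ccdc184 and Sulf2, with log2 fold changes between 3.21 and 4.04. The steepest fall was that of Gipr, the receptor for the gut hormone GIP, from 8.18 ± 0.911 to 1.19 ± 0.840 CPM (log2 fold change -2.90 ± 0.33, limma adjusted p = 1.79e-05). Aldh1l2, a mitochondrial enzyme of folate metabolism, followed at -2.45 ± 0.22, and Chac1, which degrades glutathione, at -2.12 ± 0.24. Slc7a3, a cationic amino acid transporter, had a log2 fold change of -2.03 ± 0.17. Ier3, an immediate early gene, fell from 65.9 ± 5.81 to 17.8 ± 1.74 CPM. Dpf1, Gcnt2, Tgfb3, C3 and Mcf2l completed the 10 largest falls, with log2 fold changes between -2.06 and -1.87. In the coordinates of the deposited table Tnfsf4 (ENSMUSG00000026700) lay on chromosome 1 from 161222980 to 161245981 and Gipr (ENSMUSG00000030406) on chromosome 7 from 18889986 to 18900052. The genome build of these coordinates is not given in the sources used here, and they are not those of mm10 annotation.

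Naive and central memory T cell genes were higher with urolithin A. Of 22 tested, 16 rose and 2 fell (17 and 3 adjusted over the list alone), with a median log2 fold change of 0.55. Tcf7, the transcription factor TCF-1 of naive and stem-like T cells, rose from 52.4 ± 0.677 to 130 ± 11.1 CPM (log2 fold change 1.31 ± 0.08). The chemokine receptor gene Ccr7 rose 2.06-fold, and Lef1, a partner of TCF-1, rose 1.29-fold. Igfbp4, a further member, fell by 0.46 ± 0.10 on the log2 scale. The list passed the camera test (adjusted p = 1.28e-07), with adjusted p = 0.221 with an estimated correlation. Among 10 surface genes that mark stem cell memory T cells, 6 rose and none fell, also when adjusted over the list alone. Members shared with the preceding list include Ccr7, Cd27 and Il7r. Fas rose from 25.3 ± 1.75 to 92.3 ± 9.84 CPM, while the log2 fold change of Cd28 was -0.04 ± 0.07 (limma adjusted p = 0.733). The camera adjusted p of the surface genes was 5.85e-04, and adjusted p = 0.221 with an estimated correlation. In the same libraries the B cell marker Ighm was at 156 ± 9.32 CPM with DMSO and 213 ± 21.2 CPM with urolithin A. Tcf7 (ENSMUSG00000000782) lay on chromosome 11 from 52143198 to 52174158 in the coordinates of the table.

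Wnt and beta-catenin target genes did not pass camera as a list, while fry, which does not compare them with other genes, called them higher (fry adjusted p = 0.00241). Of 12 tested, 5 rose and 3 fell (6 and 3 adjusted over the list alone), with a median log2 fold change of 0.27 and a camera adjusted p of 0.206. Among those that rose, Tcf7 and Lef1 also belong to the naive list and Cd44 to the stem memory surface genes. The call by fry is therefore not separate from those lists. Besides Tcf7, Ccnd2, which encodes a G1 cyclin, rose by 0.55 ± 0.08 on the log2 scale. Fzd7, a Wnt receptor, had a log2 fold change of -1.03 ± 0.15. Axin2, a feedback inhibitor that beta-catenin induces in many cell types, was at 12.8 ± 0.711 CPM with DMSO and 13.7 ± 0.724 CPM with urolithin A (log2 fold change 0.09 ± 0.11, limma adjusted p = 0.561). The log2 fold change of Ctnnb1, the gene of beta-catenin, was -0.01 ± 0.07 (limma adjusted p = 0.951).

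**Figure D1:**
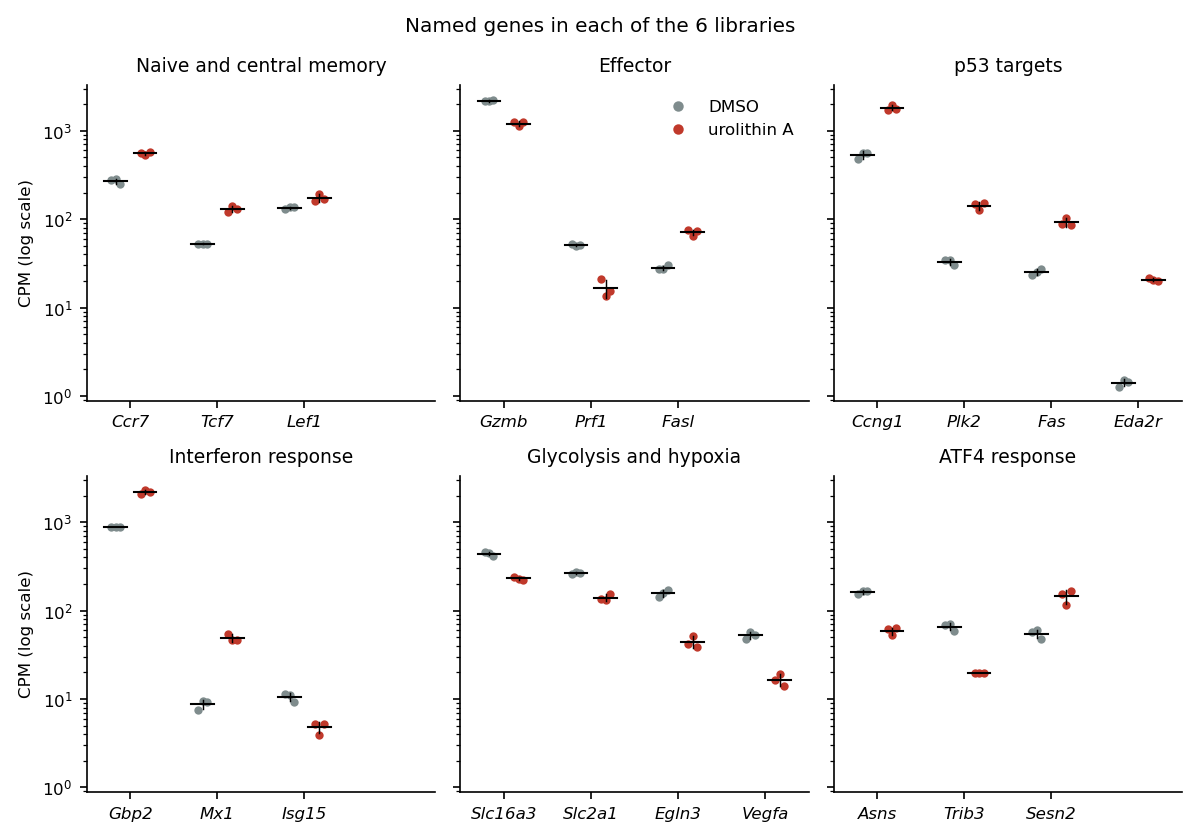
CPM of 20 named genes in each of the 6 libraries on a log axis, in 6 panels by gene list. Grey points are DMSO libraries and red points urolithin A libraries (n = 3 each), with the mean as a horizontal line and 1 SD as a vertical line. Prf1 stood at 51.0 CPM with DMSO and 16.7 CPM with urolithin A.

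Effector T cell genes moved in both directions. Of 21 tested, 8 rose and 5 fell, the same numbers as adjusted over the list alone, and the median log2 fold change of -0.03 and the mean of 0.01 differ in sign (camera adjusted p = 0.942). Gzmb, which encodes the cytotoxic protease granzyme B, fell from 2173 ± 38.9 to 1206 ± 70.2 CPM, and Prf1, the pore-forming protein perforin, from 51.0 ± 1.00 to 16.7 ± 3.99 CPM. Fasl, the death ligand, rose from 28.2 ± 1.51 to 70.9 ± 5.44 CPM (log2 fold change 1.32 ± 0.09). Among 15 inhibitory receptor and exhaustion genes, 6 rose and 5 fell (8 and 5 adjusted over the list alone), with a median of 0.28 and a camera adjusted p of 0.241. The nuclear receptor gene Nr4a3 rose 5.82-fold and Cd101 rose by 1.32 ± 0.13 on the log2 scale, while the log2 fold change of the inhibitory receptor gene Lag3 was -1.11 ± 0.11. Of 26 T cell activation genes, 5 rose and 10 fell (6 and 11 adjusted over the list alone; median -0.08, camera adjusted p = 0.206). Cd69, an early activation marker, rose 1.92-fold. Tnfrsf9, which encodes the costimulatory receptor 4-1BB, and Slc3a2, the heavy chain of amino acid transporters, had log2 fold changes of -0.87 ± 0.07 and -0.94 ± 0.09.

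T helper 2 genes were lower. Of 8 tested, 5 fell and 1 rose, the same as adjusted over the list alone, with a median log2 fold change of -0.51 and a camera adjusted p of 0.0258, while adjusted p = 0.221 with an estimated correlation. The cytokine gene Il4 fell from 13.4 ± 0.695 to 5.82 ± 0.357 CPM. The chemokine receptor genes Ccr4 and Ccr8 went apart, with log2 fold changes of -0.59 ± 0.09 and 0.38 ± 0.13. The call of Ccr8 was lost in 5 of the 6 fits that left out a library (limma adjusted p of 0.0614 to 0.153). The call of this list was lost without DMSO library b (camera adjusted p = 0.0593), without DMSO library c (adjusted p = 0.0901) and without urolithin A library b (adjusted p = 0.0546). A stricter count filter also ended it (camera adjusted p = 0.110), as did limma on log2 values of CPM with 1 (0.0755) or 0.1 added (0.0901). Of 11 regulatory T cell genes, 2 rose and 3 fell (2 and 4 adjusted over the list alone; median 0.11, camera adjusted p = 0.970). Nrp1 and Itgae rose by 1.87 ± 0.13 and 0.68 ± 0.17 on the log2 scale, while Ctla4 had a log2 fold change of -0.47 ± 0.09. Cd4 was at 250 ± 9.83 CPM with DMSO and 299 ± 12.5 CPM with urolithin A (log2 fold change 0.26 ± 0.07, limma adjusted p = 0.00923). The call of Cd4 was lost without DMSO library b (limma adjusted p = 0.0660) and without DMSO library c (adjusted p = 0.0551). Cd8a was at 116 ± 1.75 and 130 ± 1.04 CPM (log2 fold change 0.16 ± 0.07, limma adjusted p = 0.0822).

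Targets of the tumour suppressor p53 rose together. This list shares Fas with the stem memory surface genes. Of 24 tested, 21 rose and none fell (22 and 0 adjusted over the list alone), with a median log2 fold change of 1.41. Ccng1, which encodes cyclin G1, rose from 533 ± 51.6 to 1818 ± 118 CPM, and the kinase gene Plk2 from 32.9 ± 2.40 to 142 ± 14.0 CPM (log2 fold change 2.11 ± 0.09, limma adjusted p = 1.97e-09). Eda2r, a receptor of the tumour necrosis factor family, rose from 1.41 ± 0.128 to 20.6 ± 0.787 CPM. Sesn2, a stress-induced regulator of nutrient signalling, rose 2.64-fold. Plk3, a kinase related to Plk2, had the lowest value of the list, a log2 fold change of -0.19 ± 0.12 that did not pass (limma adjusted p = 0.274). The list passed camera (adjusted p = 3.62e-19) and also passed with an estimated correlation (adjusted p = 0.0284). BCL2 family and caspase genes, a list that shares Bax, Bbc3 and Pmaip1 with the p53 targets and Bcl2 with the naive list, were higher as well. Of 21 tested, 12 rose and none fell (14 and 1 adjusted over the list alone; median 0.42, camera adjusted p = 7.32e-05), while adjusted p = 0.0779 with an estimated correlation. The proapoptotic genes Pmaip1, which encodes NOXA, and Apaf1, the core of the apoptosome, rose 2.81-fold and 2.00-fold. Bcl2, which opposes apoptosis, had a log2 fold change of -0.19 ± 0.07 (limma adjusted p = 0.0695). It passed without urolithin A library b (log2 fold change of Bcl2 -0.25, limma adjusted p = 0.00161) and without ribosomal RNA genes, an alternative chosen after seeing the data (adjusted p = 0.0473).

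Interferon response genes were higher, with exceptions. Of 29 tested, 20 rose and 3 fell (21 and 3 adjusted over the list alone), with a median log2 fold change of 0.67. Gbp2, an interferon-induced GTPase, rose from 883 ± 8.37 to 2201 ± 94.2 CPM. Mx1 rose from 8.77 ± 1.07 to 49.5 ± 4.84 CPM, a 5.67-fold increase. Mx1 is known as the gene of an antiviral GTPase, but the deposited table classes it as a polymorphic pseudogene. Isg15, a ubiquitin-like protein that interferon induces, fell from 10.6 ± 1.06 to 4.77 ± 0.698 CPM. Camera called the interferon list (adjusted p = 1.26e-07), with adjusted p = 0.0779 with an estimated correlation. The Gbp and Ifit genes have close paralogs, so their counts are uncertain where reads were shared. In the same libraries Mpeg1, listed among macrophage markers, was 1.65 ± 0.18 higher on the log2 scale, while Lyz2 and Csf1r stayed under 1 CPM.

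Genes of the ATF4 pathway, which amino acid shortage and mitochondrial stress are known to induce, were lower. Of 29 tested, 24 fell and 2 rose (25 and 2 adjusted over the list alone), with a median log2 fold change of -0.84. The pseudokinase gene Trib3 fell from 65.9 ± 6.21 to 19.7 ± 0.168 CPM, and Asns, which encodes asparagine synthetase, from 161 ± 7.79 to 58.8 ± 5.61 CPM (log2 fold change -1.46 ± 0.08, limma adjusted p = 1.37e-08). Sesn2, which also belongs to the p53 list, was the member that rose most. For the list camera gave an adjusted p of 5.02e-13, and adjusted p = 0.221 with an estimated correlation.

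Glycolysis genes fell as a list. Of 21 tested, 19 fell and none rose (20 and 0 adjusted over the list alone), with a median log2 fold change of -0.58. Slc2a1, the glucose transporter GLUT1, fell from 266 ± 6.55 to 140 ± 12.6 CPM, and Slc16a3, the lactate exporter MCT4, from 443 ± 19.3 to 232 ± 9.50 CPM. The list passed camera (adjusted p = 5.02e-13) and also passed with an estimated correlation (adjusted p = 0.0284). Hypoxia response genes, which share Slc2a1 with the glycolysis list, were lower too. Of 21 tested, 17 fell and none rose (18 and 0 adjusted over the list alone; median -0.83). Egln3, a prolyl hydroxylase that HIF induces, fell from 157 ± 15.4 to 44.4 ± 6.98 CPM, and Vegfa, an angiogenic growth factor, from 52.6 ± 4.92 to 16.6 ± 2.57 CPM. In camera the hypoxia list had an adjusted p of 6.63e-12, and adjusted p = 0.221 with an estimated correlation.

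Ribosome biogenesis genes were lower. Of 25 tested, 21 fell and 1 rose, the same as adjusted over the list alone, with a median log2 fold change of -0.55. The nucleolar genes Wdr43 and Gnl3 both had log2 fold changes of -0.70 ± 0.07, and Utp20 rose by 0.38 ± 0.09. Camera called the ribosome biogenesis list (adjusted p = 5.06e-10), with adjusted p = 0.334 with an estimated correlation. Of 61 cytosolic ribosomal protein genes, 22 fell and 2 rose, the same as adjusted over the list alone (median -0.18, camera adjusted p = 2.94e-05), while adjusted p = 0.221 with an estimated correlation. Rpl3 and Rps18 had log2 fold changes of -0.72 ± 0.08 and -0.89 ± 0.11, and Rpl15 rose by 0.73 ± 0.08. These genes have many processed pseudogenes, so their counts are uncertain. Cholesterol biosynthesis and uptake genes were lower in 15 of 23 tested, and none rose, also when adjusted over the list alone (median -0.25). Lss and Sqle, which act at successive steps around squalene, had log2 fold changes of -0.63 ± 0.07 and -0.47 ± 0.07, and Tm7sf2 had 0.15 ± 0.12 (limma adjusted p = 0.344). Without urolithin A library b Tm7sf2 passed at 0.25 (limma adjusted p = 0.0486). The camera adjusted p of the cholesterol genes was 2.55e-05, and adjusted p = 0.221 with an estimated correlation.

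**Figure D2:**
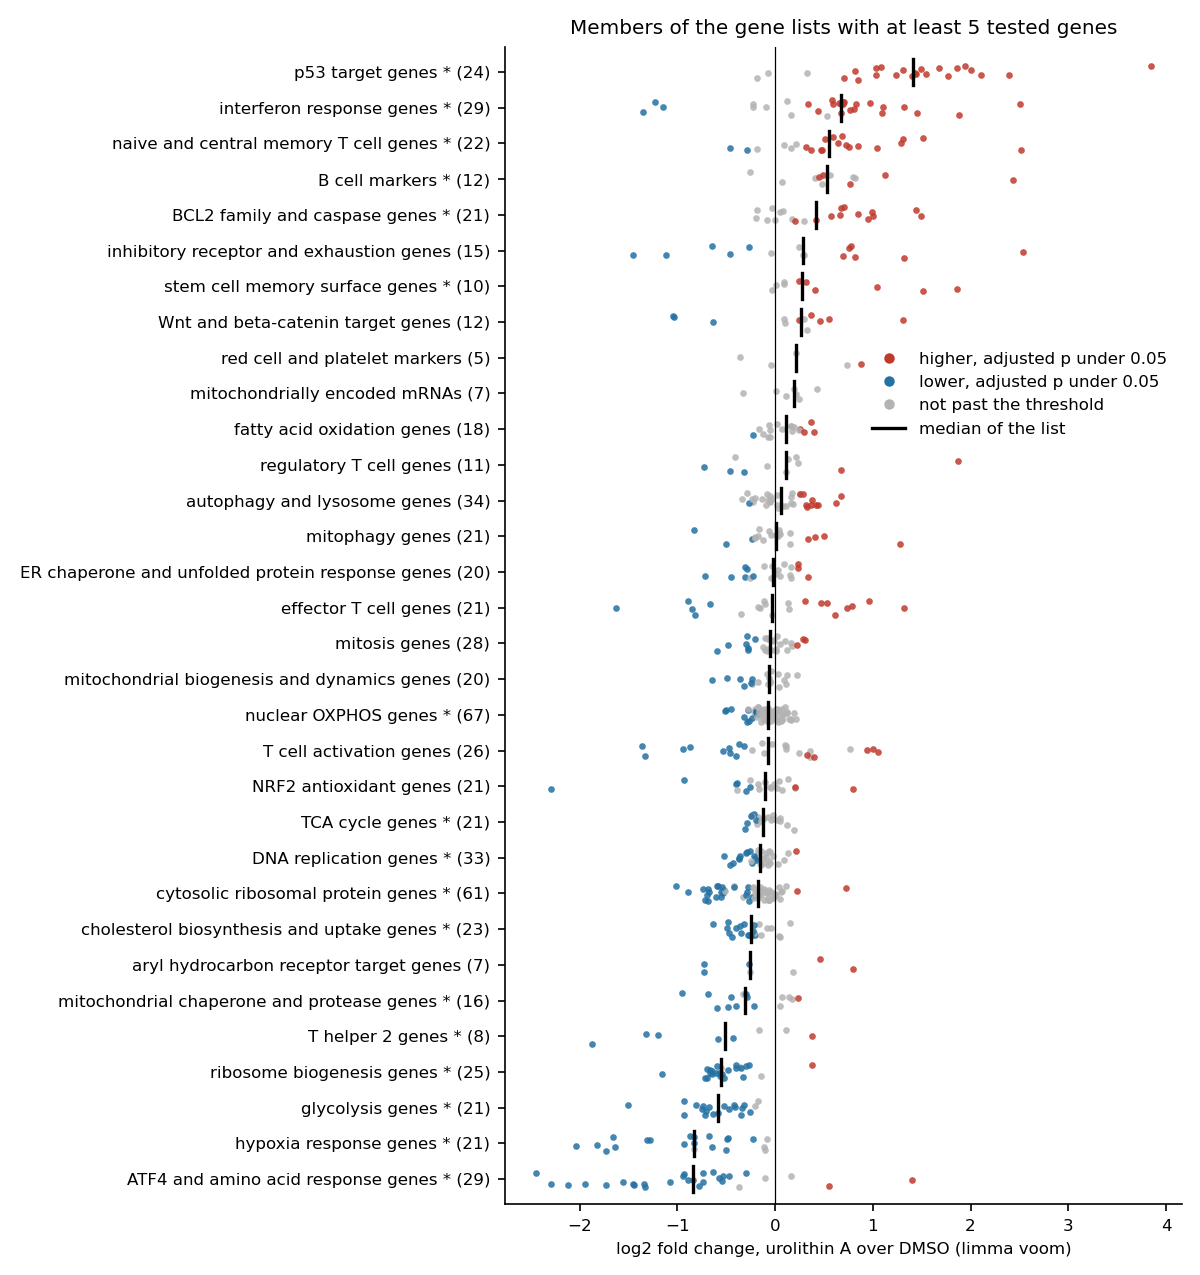
Log2 fold change (urolithin A over DMSO, limma voom) of the tested members of the 32 gene lists, ordered by list median. Each point is a gene, coloured by its own adjusted p, the black line is the median, an asterisk marks lists with a camera adjusted p under 0.05 and the number of tested genes stands in parentheses. The median was 1.41 for p53 target genes at the top and -0.84 for ATF4 genes at the bottom.

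Mitophagy genes did not move as a list. Of 21 tested, 4 rose and 3 fell, the same as adjusted over the list alone. Their median log2 fold change of 0.005 and mean of 0.020 were above 0 while camera gave the direction as down (adjusted p = 0.970). Pink1, the kinase that marks damaged mitochondria, rose from 34.9 ± 2.72 to 49.0 ± 1.31 CPM (log2 fold change 0.50 ± 0.09, limma adjusted p = 4.77e-04). Calcoco1, an autophagy receptor, rose 2.42-fold, while Bnip3, a mitophagy receptor that hypoxia induces, fell from 54.4 ± 4.56 to 30.6 ± 5.20 CPM. The mitochondrial phosphatase gene Pgam5 had a log2 fold change of -0.23 ± 0.07 (limma adjusted p = 0.0244). The call of Pgam5 was lost without DMSO library b (limma adjusted p = 0.101), without DMSO library c (adjusted p = 0.0540) and without urolithin A library a (adjusted p = 0.0589). Of 34 autophagy and lysosome genes, 10 rose and 1 fell, the same as adjusted over the list alone (median 0.06, camera adjusted p = 0.206). Fnip1, a regulator of nutrient signalling at the lysosome, and Ulk1, the kinase that starts autophagy, rose by 0.68 ± 0.07 and 0.62 ± 0.12 on the log2 scale, and Atg16l1 fell by 0.27 ± 0.07. The call of Atg16l1 was lost when libraries were scaled to their total count alone (limma adjusted p = 0.425).

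Nuclear genes of oxidative phosphorylation changed little. Of 67 tested, 11 fell and none rose (2 and 0 adjusted over the list alone). The median log2 fold change was -0.07, -0.04 without urolithin A library a, and 0.02 when libraries were scaled to their total count alone. The camera adjusted p was 0.0445, and adjusted p = 0.658 with an estimated correlation. Uqcrq and Ndufs7 had log2 fold changes of -0.51 ± 0.08 and -0.45 ± 0.10, and Ndufa7 had 0.16 ± 0.08 (limma adjusted p = 0.146). Of 21 tricarboxylic acid (TCA) cycle genes, 6 fell and none rose, also when adjusted over the list alone (median -0.12, camera adjusted p = 0.0445), while adjusted p = 0.658 with an estimated correlation. Idh3b and Idh3a, subunits of isocitrate dehydrogenase, had log2 fold changes of -0.29 ± 0.07 and -0.31 ± 0.08, and Ogdh had 0.20 ± 0.09 (limma adjusted p = 0.111). Without urolithin A library b Ogdh passed at 0.31 (limma adjusted p = 3.67e-04). Both lists lost their call with a stricter count filter (camera adjusted p = 0.126 and 0.110). They also lost it with limma on log2 values of CPM with 1 (0.0727 each) or 0.1 added (0.0643 each), and with the letter as a block (0.0589 each). With protein-coding genes only, an alternative chosen after seeing the data, camera adjusted p was 0.0647 and 0.0636. The oxidative phosphorylation list further lost its call without DMSO library c (camera adjusted p = 0.0959), urolithin A library a (0.421) or urolithin A library b (0.0575). For the TCA list the same held without DMSO library b (camera adjusted p = 0.0721), DMSO library c (0.0527), urolithin A library a (0.0833) or urolithin A library b (0.217). None of the 7 mitochondrially encoded mRNAs tested passed, also when adjusted over the list alone (median 0.19, camera adjusted p = 0.649). Their log2 fold changes had wide errors, as 0.43 ± 0.34 for mt-Cytb, 0.25 ± 0.28 for mt-Nd4 and -0.33 ± 0.29 for mt-Nd6. With libraries scaled to their total count alone, mt-Cytb passed (log2 fold change 0.52, limma adjusted p = 0.0241).

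Mitochondrial chaperone and protease genes were lower. Of 16 tested, 10 fell and 1 rose (11 and 1 adjusted over the list alone), with a median log2 fold change of -0.30. Lonp1, the main protease of the mitochondrial matrix, fell from 567 ± 27.1 to 294 ± 19.9 CPM, and Afg3l2, a protease of the inner membrane, had a log2 fold change of -0.69 ± 0.07. Clpx rose by 0.24 ± 0.08, a call lost without DMSO library a (limma adjusted p = 0.150), DMSO library c (0.0763), urolithin A library a (0.0885) or urolithin A library c (0.0585). The camera adjusted p of the list was 0.00287, and adjusted p = 0.366 with an estimated correlation. Of 20 mitochondrial biogenesis and dynamics genes, 6 fell and none rose, also when adjusted over the list alone (median -0.07, camera adjusted p = 0.0982). The transcriptional regulators Nrf1 and Pprc1 had log2 fold changes of -0.49 ± 0.07 and -0.65 ± 0.13, and Polg2 had 0.22 ± 0.11 (limma adjusted p = 0.143). Of 18 fatty acid oxidation genes, 4 rose and 1 fell, the same as adjusted over the list alone (median 0.12, camera adjusted p = 0.206). Eci2 and Decr1, which handle unsaturated fatty acids, rose 1.32-fold and 1.29-fold. Acaa2 had a log2 fold change of -0.23 ± 0.08, a call lost without any of DMSO library a (limma adjusted p = 0.0990), b (0.0967) or c (0.0838) or urolithin A library a (0.163).

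DNA replication genes were slightly lower. Of 33 tested, 13 fell and 1 rose (15 and 1 adjusted over the list alone), with a median log2 fold change of -0.16 and a camera adjusted p of 4.28e-04, while adjusted p = 0.328 with an estimated correlation. Dut and Ccne1, the gene of cyclin E1, had log2 fold changes of -0.43 ± 0.07 and -0.47 ± 0.08. Gins1 had 0.22 ± 0.08 (limma adjusted p = 0.0483), a call lost in 5 of the 6 fits that left out a library (adjusted p of 0.0649 to 0.231). Of 28 mitosis genes, 3 rose and 7 fell, the same as adjusted over the list alone (median -0.05, camera adjusted p = 0.257). Mybl2 and Plk1 had log2 fold changes of -0.59 ± 0.09 and -0.48 ± 0.09, and Ccnb2 rose by 0.30 ± 0.07.

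Of 20 endoplasmic reticulum chaperone and unfolded protein response genes, 3 rose and 6 fell (4 and 7 adjusted over the list alone; median -0.02, camera adjusted p = 0.481). Herpud1 and Xbp1 had log2 fold changes of -0.72 ± 0.08 and -0.45 ± 0.06, and Edem1 rose by 0.34 ± 0.06. Of 21 antioxidant genes controlled by NRF2, 2 rose and 6 fell, the same as adjusted over the list alone (median -0.10, camera adjusted p = 0.154). Slc7a11, the cystine transporter that ATF4 also induces, fell from 3.95 ± 0.165 to 0.858 ± 0.357 CPM, and Tkt had a log2 fold change of -0.39 ± 0.09. Nqo1 rose from 2.37 ± 0.171 to 4.32 ± 1.09 CPM (limma adjusted p = 0.0120), a call lost without DMSO library a (adjusted p = 0.0561). Of 7 targets of the aryl hydrocarbon receptor, 2 rose and 3 fell, the same as adjusted over the list alone (median -0.26, camera adjusted p = 0.649). Tiparp and Il10 both had log2 fold changes of -0.73, with errors of 0.15 and 0.19, and Nfe2l2 rose by 0.46 ± 0.09. The call of Il10 was lost without DMSO library c (limma adjusted p = 0.0540). The receptor gene Ahr was at 4.11 ± 0.489 and 4.62 ± 0.448 CPM (limma adjusted p = 0.445). Its classical target Cyp1a1 had 3 to 11 counts per library and could not be tested at this depth.

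B cell markers were higher with urolithin A. Of 12 tested, 5 rose and none fell, also when adjusted over the list alone (median 0.53, camera adjusted p = 0.0193), while adjusted p = 0.221 with an estimated correlation. Ighm rose 1.36-fold, and Jchain was at 0.168 ± 0.113 CPM with DMSO and 0.980 ± 0.412 CPM with urolithin A (log2 fold change 2.44 ± 0.53, limma adjusted p = 0.00251). Ighm was at a mean of 156 CPM with DMSO and 213 CPM with urolithin A, while Igkc was at 3.01 and 6.44, Ms4a1 at 2.03 and 3.54 and Cd79a at 0.698 and 1.15 CPM, genes picked after their values were seen. Cd22 had a log2 fold change of -0.25 ± 0.36 (limma adjusted p = 0.624). The call of this list was lost without urolithin A library b (camera adjusted p = 0.151) and without urolithin A library c (adjusted p = 0.0516). Of 5 red cell and platelet markers tested, 1 rose, and none passed adjusted over the list alone (median 0.21, camera adjusted p = 0.649). That gene was Hbb-bs, at 1.31 ± 0.455 and 2.32 ± 0.436 CPM, whose call was lost without DMSO library a (limma adjusted p = 0.0587), DMSO library c (0.201), urolithin A library a (0.0757) or urolithin A library c (0.0854). Alas2 and Pf4 had log2 fold changes of 0.74 ± 0.34 (limma adjusted p = 0.111) and -0.36 ± 0.28 (adjusted p = 0.348). The other 9 lists had fewer than 5 tested members and were not tested as lists. Among them, 2 of 3 T helper 17 genes, 1 of 3 CD4 T cell markers, 1 of 2 macrophage and monocyte markers, 1 of 2 dendritic cell markers and 1 of 4 stromal and endothelial markers rose. None of 4 CD8 T cell markers, 2 gamma delta T cell markers and 2 natural killer cell markers passed, and no neutrophil marker had enough counts to be tested. Adjusted over the list alone, 1 natural killer cell marker rose and 1 dendritic cell marker fell as well.

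Of the 32 lists tested, 17 passed camera at its preset correlation, 6 higher and 11 lower, and 2 of them, the p53 targets and the glycolysis genes, also passed with an estimated correlation. The self-contained test fry, which asks whether a list's own genes move on balance in a direction, called 21 lists. Besides the Wnt targets it called 5 lists that camera did not. The inhibitory receptor (fry adjusted p = 0.00472), regulatory T cell (0.0146), autophagy (0.0155) and fatty acid oxidation lists (0.0197) were called higher, and the mitochondrial biogenesis list (0.0298) lower. It did not call the oxidative phosphorylation (fry adjusted p = 0.203) and TCA cycle lists (0.1299). The mixed form of fry, which asks whether genes change in either direction, called 31 lists, all but the mitochondrially encoded mRNAs. The inhibitory receptor list passed camera without the members it shares with other lists (adjusted p = 0.0485), an alternative chosen after seeing the data.

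Several named genes lost their call when libraries were scaled to their total count alone. Besides Atg16l1 these were Igfbp4 (limma adjusted p = 0.0960), Ndufs7 (0.0676), Idh3b (0.332), Idh3a (0.296), Tkt (0.102) and Dut (0.0581). The same held for Clpx (limma adjusted p = 0.0862), Acaa2 (0.543), Gins1 (0.127), Pgam5 (0.526) and Cd4 (0.0527). Camera lost the oxidative phosphorylation list (adjusted p = 0.304), the TCA cycle list (0.340) and the B cell list (0.0610) in that scaling. Besides that of oxidative phosphorylation, the medians of 4 called lists moved by over 1.5 times there, the TCA cycle from -0.12 to -0.03, DNA replication from -0.16 to -0.07, cholesterol from -0.25 to -0.16 and cytosolic ribosomal proteins from -0.18 to -0.08. Without DMSO library b and urolithin A library a the calls of Atg16l1 (limma adjusted p = 0.104), Idh3b (0.0510), Idh3a (0.120), Il10 (0.0655) and Itgae (0.0537) were lost. In that fit Clpx (limma adjusted p = 0.105), Acaa2 (0.311), Gins1 (0.284), Ccr8 (0.185), Hbb-bs (0.0727), Pgam5 (0.218) and Cd4 (0.0920) were lost too. So were, in camera, the oxidative phosphorylation list (adjusted p = 0.328), the TCA cycle list (0.161) and the T helper 2 and B cell lists (0.0526 each). With limma on log2 values of CPM with 5 added, camera lost the T helper 2 list (median -0.28 instead of -0.51, adjusted p = 0.0690) and the B cell list (0.14 instead of 0.53), with the oxidative phosphorylation and TCA cycle lists (adjusted p = 0.0646 for these 3). Cd8a passed with a stricter count filter (limma adjusted p = 0.0451).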

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

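Across 23 alternatives no gene or list was called in the opposite direction, among 2378 values of named genes (2245 same, 127 weaker, 6 stronger) and 661 of lists (600 same, 54 weaker, 7 stronger). Most of these genes were named for a small p or a large change in these same data. The stricter thresholds reuse the main fit and cannot reverse a value. The other alternatives use the same libraries or most of them, so reversed calls were unlikely there too. Of 103 called named genes, 86 kept their call in all of the 18 alternatives with the main threshold that tested them, 96 had an adjusted p under 0.01 and 47 changed at least 2-fold. The median of the oxidative phosphorylation list turned from -0.07 to 0.02 with library size alone, where it was not called. Medians near 0 of lists that were not called changed sign in some alternatives, such as T cell activation (-0.08 to 0.01), mitochondrial biogenesis (-0.07 to 0.02), mitosis (-0.05 to 0.03) and endoplasmic reticulum genes (-0.02 to 0.07) with library size alone, and mitochondrially encoded mRNAs (0.19 to -0.13) without urolithin A library b. With library size alone 3169 genes were called instead of 4871, with 932 lower and 70.6% higher against 52.6%. The median log2 fold change of all tested genes was 0.095 there, against 0.0064 with the main scaling. DMSO library b, with 17.6% of its counts in Rn18s, had a scaling factor of 0.832, against 1.01 to 1.05 elsewhere. Library size alone omits this factor, so the other genes of that library were scaled lower. Whether this accounts for every lost call was not tested. An adjusted p under 0.01 left 3091 genes (1682 higher, 1409 lower), and a change of at least 2-fold 910 (609 and 301), as stricter thresholds must. Without DMSO library b and urolithin A library a, an alternative chosen after seeing the data, 2522 were called (1330 and 1192) from fewer libraries. All 2493 shared with the full fit kept their direction, which the reuse of the same libraries made likely. Leaving out each library in turn gave 3485 to 5140 genes (1803 to 2684 higher, 1682 to 2456 lower) and 13 to 17 lists. With an estimated correlation 2 lists were called instead of 17. Adjusted p rose there also for lists whose estimated correlation lay below the preset 0.01. The values were 0.0023 for glycolysis, -0.026 for the BCL2 family, -0.046 for T helper 2 and -0.012 for B cell lists. For these, more shared variation than preset within the list cannot be the reason. Camera with an estimated correlation also uses the few residual degrees of freedom of the 6 libraries. Fewer degrees of freedom give a larger p for the same statistic. How much of the rise this makes up was not tested. Wherever tested in the other alternatives 13 of the 17 were kept, the others being the oxidative phosphorylation, TCA cycle, T helper 2 and B cell lists. With the letter as a replicate block 4496 genes were called and 15 lists. The block ended the calls of the oxidative phosphorylation and TCA cycle lists (camera adjusted p = 0.0589 each). It also ended those of Acaa2 (limma adjusted p = 0.0569), Gins1 (0.0658) and Hbb-bs (0.0619). Same-letter libraries correlated in their deviations with r of 0.09, -0.19 and -0.10, and 1 of 6 correlated best with its own letter. Limma with a trend on log2(CPM + 1) called 4863 genes, 4713 of them shared. In that fit camera lost the oxidative phosphorylation and TCA cycle lists (adjusted p = 0.0727 each) and the T helper 2 list (0.0755). Gins1 lost its call there too (limma adjusted p = 0.0504). The alternatives without ribosomal RNA genes, with protein-coding genes only and with lists without shared members were also chosen after seeing the data. The planned edgeR and DESeq2 fits were not run. Genes with few counts, such as Cyp1a1, could not be tested at this depth.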

Other observations

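Gene families by shared symbol were looked at after the values were seen, so their p-values only order them. Some families share members with the fixed lists, as Gbp2 with the interferon list, and are not separate support for those lists. Of 196 families with at least 8 tested members, camera called 25, with 6 higher and 19 lower, and every one had adjusted p = 0.789 with an estimated correlation. All 10 tested Gbp genes, interferon-induced GTPases, rose, with a median log2 fold change of 1.20, and Gbp8 rose by 1.57 ± 0.11 and Gbp10 by 1.38 ± 0.09. These genes are near-identical copies in part, so their counts are uncertain. Among 12 Parp genes 8 rose and 2 fell, with Parp8 at 1.73 ± 0.11 and Parp11 at 1.33 ± 0.08. Among 8 tumour necrosis factor ligand genes 4 rose and 1 fell, and Tnfsf8, which encodes the ligand of CD30, rose from 29.2 to 170 CPM.

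Several of the 19 lower families hold genes of translation, RNA processing or transport, a grouping that was not tested. Of 35 tRNA synthetase genes 19 fell and 2 rose (median -0.32), with Sars and Nars both at -0.78. Of 53 Eif genes 28 fell and 5 rose (median -0.25), and Eif4ebp1, a repressor of translation that ATF4 induces, had -1.34 ± 0.09. Of 48 Mrpl genes, which encode mitochondrial ribosomal proteins, 21 fell and none rose. Of 8 Slc7a amino acid transporter genes 6 fell, and of 9 Slc16a monocarboxylate transporter genes 5 fell, with Slc16a1 at -0.68 ± 0.07. Sars, Eif4ebp1, Slc7a1, Slc7a5 and Slc7a11 also belong to the ATF4 list, and Slc16a1 and Slc16a3 to the glycolysis list.

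The predictions of the tests that follow were written before their values were computed. The p53 target genes may have risen through p53 activity, and 3 other explanations were tested. Carry-over of ribosomal RNA predicted a median of 0.5 or less without DMSO library b and urolithin A library a, and it was 1.4139 against 1.41481 with all libraries. Removing the trend on gene length and GC content left a median of 1.37. Both values stayed above the bound of 1 and argue against these 2 explanations. More Trp53 transcript was not seen, as its log2 fold change was -0.0078 (95% interval -0.23 to 0.22). Protein activity of p53 was not measured, so the cause stays open.

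The lower glycolysis, hypoxia, ATF4 and ribosome biogenesis genes may share a cause. Over their 94 members the median log2 fold change was -0.647, without the library of each group with most 18S counts -0.644, and after removing the trend on length and GC content -0.678. The last 2 values stayed below the bound of -0.4 and argue against ribosomal RNA carry-over and against length and GC bias as the cause. Myc, a known activator of many of these genes, had a log2 fold change of -0.636 (95% interval -0.87 to -0.40). Less Myc transcript remains possible, and causes that were not tested stay open too.

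The higher B cell markers may come from more B cells left among the T cells. The median log2 fold change of 10 abundant B cell transcripts was 0.782 and that of the 5 called markers 0.767, but 3 of the 5 belong to both sets, so the comparison decides nothing. Cell shares were not measured, and the explanation stays open.

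The 6 libraries can be split into 3 and 3 in 10 ways. Each of the 9 other splits joins 2 libraries of a treatment with 1 of the other on each side. Part of the treatment difference therefore remains between the sides, and it also adds to the spread within them. The real split called 4871 genes and the highest other split 0, so 1 split had as many. For the lists the real split called 17 and the highest other split also 17, so 2 splits had as many. A comparison list by list, chosen after the values were seen, found the smallest p in the real split for 12 of the 17 lists, among them the p53 targets at 3.62e-19 against 8.03e-06 in the next. Each of the 17 lists was also called in at least 1 other split, and the p53 list in all 9 of them. For 5 lists, oxidative phosphorylation, TCA cycle, mitochondrial chaperones, DNA replication and cytosolic ribosomal proteins, another split had a smaller p. Since no other split is free of the treatment, list calls in the other splits do not show how often chance alone gives such calls. The 0 genes called in the other splits do not show it either.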
